A study of Mus musculus with 12 samples.

How the data were processed

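The series holds 12 samples of mouse CT26 material, of which 6 are analysed here: bulk RNA-seq of cultured CT26 cells, 3 libraries of Mll3 wild-type cells and 3 of Mll3 knock-out cells. CT26 is a colorectal carcinoma line of BALB/c mice, and Mll3 is the older name of Kmt2c, a histone H3 lysine methyltransferase. The CUT&Tag and single-cell samples of the series are not analysed here.

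The values are whole-number read counts per Ensembl gene as deposited by the authors, in 1 table of 17718 genes. Per the labels' protocols, strand-specific polyA libraries were made with a directional kit and all 6 carry the same batch date. Per the submitters' processing notes, fastp, STAR, HTSeq, Bowtie2, deepTools and SEACR were used with genome build mm10, with no role or version stated; the annotation release and the strand setting of the counting are not given in the sources used here. Every gene of the table is above 0 in at least 3 libraries, so genes seen in fewer had been left out before deposit. Wild-type columns were matched to their samples by group and number. The knock-out columns carry a short form that is usual for single guide RNA plus a number, and the labels do not say whether that number is a replicate or a guide, so they were assigned to the group without a replicate number.

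Total counts ran from 9559658 to 13406013 per library, where 1 count is 0.0746 to 0.105 CPM, the unit of counts scaled by library size. Symbols were found for 17650 identifiers, and positions of 11923 tested genes were taken from RefSeq on GRCm38.p6, the assembly of mm10, by symbol. Genes were kept with edgeR's filterByExpr (minimum count 10, minimum total 15), which left 13013, and were scaled with TMM factors. The test was edgeR's quasi-likelihood F test (edgeR 4.0.16, limma 3.58.1, R 4.3.3), with robust estimation and Benjamini-Hochberg adjustment over all genes tested at a threshold of 0.05. Log2 fold changes are knock-out over wild-type, a rise or fall given without a unit is on the log2 scale, and standard errors (SE) were derived from the F statistic. CPM values are TMM-scaled and given as mean ± SD over 3 libraries per group. Where a group had 0 counts, the fold is given as a bound against a floor of 3 counts per library; where it had 1 to 3 counts, the ratio of summed counts is given with an exact binomial 95% interval. These floors and intervals cover counting error only.

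Gene lists were tested with camera at its preset correlation of 0.01, which asks whether the members differ from the other genes tested, for lists with at least 5 tested members, with adjustment over lists. The 36 lists cover MLL3 complexes, interferon and antigen presentation, signalling, cell cycle, DNA repair, metabolism, stress, differentiation and markers of other cell types. Camera with an estimated correlation and fry were run beside it; fry asks whether a list's genes move, on balance, one way, without comparing them with other genes. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Kmt2c, the 12 largest rises and the 12 largest falls past the threshold (average log2 CPM of at least 1, groups that do not overlap, no predicted names), the 4 members with the smallest p of each list past the camera threshold and 2 of each other list, and 13 genes of antigen presentation, interferon signalling and the MLL3 and MLL4 complexes; together 132 genes. Any other gene named was chosen after its values were seen, as was the summary by chromosome.

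The pipeline was tested on simulated counts for the 13013 genes of this comparison, with 50 genes changed at each fold. It recovered 23 of 50 at 1.25-fold, 38 at 1.5-fold, 44 at 2-fold and 49 at 4-fold, and called 6 of 12813 unchanged genes. Camera called 0 of 35 unchanged simulated lists. The simulated genes were independent and few were changed, so this does not show how often camera errs on genes that move together. Library pairs within a group differed by a median of 2.13 to 3.04 times the variance that counting alone gives, so no pair was merged. Nothing states that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. Alternatives were other scalings (RLE, upper-quartile, library size alone), other filters, DESeq2 1.42.0, limma voom, glmTreat against a 1.5-fold change, an adjusted p of 0.01, removal of the 50 most abundant genes, each library left out in turn and, chosen later, removal of chromosome medians. Upper-quartile scaling and library size alone moved the median log2 fold change of the tested genes from 0.02 to 0.17 and 0.14.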

Results

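Gene expression was measured by RNA-seq in cultured CT26 cells with wild-type or knocked-out Mll3, with 3 libraries per genotype. The series addresses MLL3 mutation in tumours and its relation to immunotherapy, and the comparison asks which transcripts differ between the genotypes in the cells themselves. Wild-type libraries 1, 2 and 3 held 13406013, 10278950 and 9559658 counts, and the knock-out libraries held 9786242, 11129754 and 10001732. The share of mitochondrially encoded counts was 3.20% to 3.44% in wild-type and 3.44% to 3.81% in knock-out libraries, and that of ribosomal protein genes was 5.48% to 5.73% and 5.17% to 5.37%.

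The targeted gene, Kmt2c (ENSMUSG00000038056, chromosome 5, 25271795 to 25498855, mm10), stood at 24.9 to 26.2 CPM in the wild-type libraries and at 16.0, 11.2 and 14.8 CPM in the knock-out libraries. Its transcript was 1.82-fold lower in the knock-out (log2 fold change -0.87, SE 0.129, n = 3 per group, edgeR adjusted p = 4.33e-08). A count over the whole gene does not show where the gene was edited. Of 9 tested members of the MLL3 and MLL4 complexes, 2 rose and 5 fell (2 and 5 adjusted over the list alone), and camera did not separate the list from other genes (adjusted p = 0.490). Wdr5 and Ash2l, core subunits, fell (log2 fold changes -0.57, SE 0.0486, and -0.41, SE 0.0520). Ash2l lies on chromosome 8, whose median was -0.42, and with chromosome medians removed its value was 0.0055 (edgeR adjusted p = 0.936). Kmt2d, the paralogous methyltransferase of the MLL4 complex, had a log2 fold change of 0.12 (SE 0.0667, adjusted p = 0.0966); it passed the threshold without wild-type replicate 3 (0.18, adjusted p = 0.0160), with the stricter filter (0.16), with library size alone (0.25) and with upper-quartile scaling (0.28). Kdm6a, the H3K27 demethylase of both complexes, had -0.15 (SE 0.116, adjusted p = 0.256), which passed without 1 of the knock-out libraries (-0.30, adjusted p = 0.0411). Among 9 other COMPASS methyltransferases and partners, 3 rose and 3 fell on both adjustments (camera adjusted p = 0.886). The median of the list was -0.02, and it was 0.14 with upper-quartile scaling and 0.10 with library size alone. Cxxc1, on chromosome 18, fell (-0.81, SE 0.101), and with chromosome medians removed its value was -0.41. The genes of its region of chromosome 18 had a median of -0.85, so its fall was not larger than that of its region. Hcfc1 rose (0.37, SE 0.0483).

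Of 13013 genes tested, 8621 (66.2%) differed between the genotypes, 4301 higher and 4320 lower in the knock-out (edgeR quasi-likelihood test, adjusted p under 0.05). Of these 8621 genes, 4322 changed by under 1.5-fold and 1965 by at least 2-fold, and of the latter 1316 rose and 649 fell. With the stricter filter the 2-fold changes were 773 higher and 475 lower, and with upper-quartile scaling 1677 and 442. The 3 libraries of a genotype were close to each other, with a biological coefficient of variation of 5.03%. Wild-type replicate 3 differed more from the other wild-type libraries at the most abundant genes. The first principal component, which parts the genotypes, held 81.6% of the variance. The groups did not overlap for 8934 genes (68.7%), where chance gives 10%. Against a 1.5-fold change, glmTreat called 2602 genes, 1448 higher and 1154 lower. The higher share of the calls was 49.9% with TMM, 60.5% with library size alone and 63.7% with upper-quartile scaling, so directions of small changes are relative to the TMM scale.

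**Figure D1:**
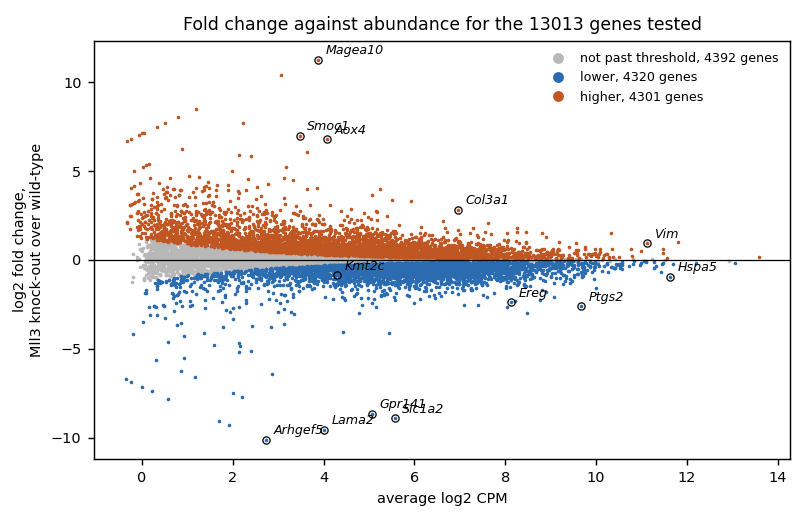
Each point is 1 of 13013 genes, with its average log2 CPM over the 6 libraries on the horizontal axis and its log2 fold change (knock-out over wild-type) on the vertical axis; 4301 genes past the threshold are higher and 4320 lower. Slc1a2 and Gpr141 lie near -9 at moderate abundance, and Ptgs2 at -2.60 is among the abundant genes that fell.

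Several genes were nearly confined to 1 genotype. Magea10, a cancer-testis antigen gene on the X chromosome, had 0 counts in wild-type and 28.9 ± 2.60 CPM in the knock-out, at least 100-fold higher. Zfp804a and Atp2b4, a plasma membrane calcium pump, also had 0 counts in wild-type and were at least 56.0-fold and 14.4-fold higher. Smoc1, a secreted calcium-binding matricellular protein, rose from 0.156 ± 0.0481 to 21.6 ± 1.01 CPM, and Aox4, an aldehyde oxidase, from 0.269 ± 0.146 to 32.9 ± 0.247 CPM. The other large rises were Platr14, Cyfip2, Rac2, Hdgfl3, Acta2 (smooth muscle actin) and the antisense genes Ptprtos and Kank4os, with log2 fold changes from 4.67 to 6.08; the antisense genes are uncertain because the strand setting of the counting is not stated.

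In the other direction, Arhgef5 stood at 12.8 ± 2.58 CPM in wild-type and had 0 counts in the knock-out, at least 45.6-fold lower. Sfmbt2, a Polycomb group gene, was at least 22.2-fold lower. Lama2, the laminin alpha 2 chain, went from 32.1 ± 1.82 CPM to 1 count, a ratio of 1039 (95% interval 186 to 41086). The glutamate transporter gene Slc1a2 fell from 94.3 ± 3.28 to 0.180 ± 0.144 CPM, and the orphan receptor gene Gpr141 from 67.1 ± 2.93 to 0.156 ± 0.148 CPM. Lonrf1 and Dapk1, a death-associated kinase, also kept 1 count, with ratios of 248 (44.1 to 9832) and 134 (23.6 to 5315). Ank2, Ostn, D5Ertd615e, Cass4 and the non-classical class I gene H2-T23 fell as well, with log2 fold changes of -6.41, -5.20, -4.86, -4.80 and -5.12. Class I genes share reads with close paralogs, and BALB/c cells carry another haplotype than the C57BL/6 reference, so their levels are uncertain.

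**Figure D2:**
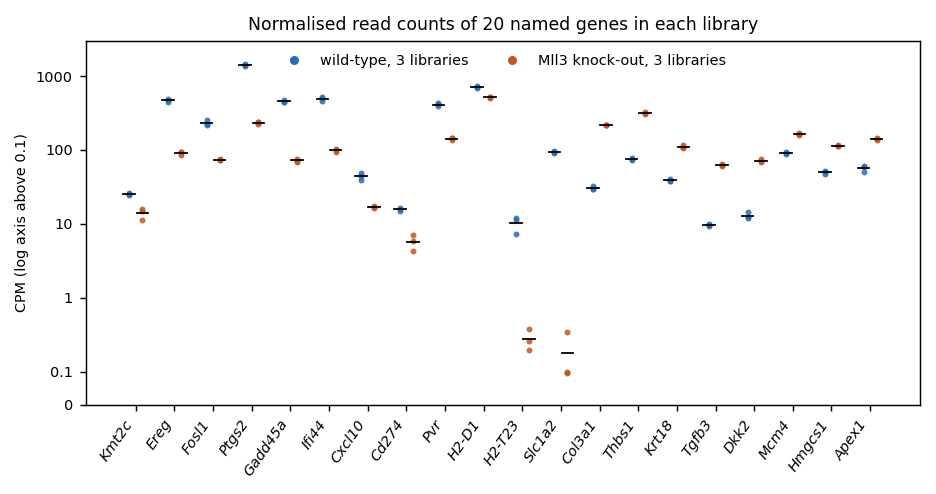
CPM of 20 named genes in each library, on an axis that is logarithmic above 0.1; blue points are the 3 wild-type and orange points the 3 knock-out libraries, and black bars are group means. For each of these genes the groups do not overlap, from H2-D1 (708 and 514 CPM) to Slc1a2 (94.3 and 0.180 CPM).

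Among signalling genes, targets of the MAPK pathway fell together. Of 29 tested MAPK and immediate early genes, 20 fell and 5 rose (20 and 6 adjusted over the list alone), with a median log2 fold change of -0.84. Ereg, the EGFR ligand epiregulin, fell from 470 ± 17.0 to 91.3 ± 5.38 CPM, a log2 fold change of -2.36. Fosl1, an AP-1 subunit, fell by 1.64, Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, by 1.59, and Epha2, an ephrin receptor, by 1.35 on the log2 scale. Camera called the list at the preset correlation (adjusted p = 2.81e-11) and with an estimated one (adjusted p = 0.0239).

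Interferon response genes were lower in the knock-out. Of 40 type I interferon response genes, 31 fell and 4 rose (31 and 4 adjusted over the list alone), with a median log2 fold change of -0.69 (camera adjusted p = 2.82e-13; adjusted p = 0.135 with an estimated correlation). Ifi44 fell from 495 ± 32.4 to 98.6 ± 4.14 CPM (log2 fold change -2.33). It lies in a region of chromosome 3 whose genes had a median of -0.78. Usp18, the ISG15-specific protease, and the oligoadenylate synthetase family genes Oasl2 and Oas1a had log2 fold changes of -1.40, -1.23 and -1.44. Of 23 interferon gamma response genes, 13 fell and 3 rose on both adjustments, with a median of -0.79 (camera adjusted p = 0.0158; adjusted p = 0.512 with an estimated correlation). The T cell attractant Cxcl10 fell by 1.39, Wars by 0.84 and the GTPase genes Irgm1 and Irgm2 by 1.03 and 1.08, while Irf1 rose from 22.5 ± 3.45 to 44.1 ± 2.99 CPM. Of 17 interferon receptor and nucleic acid sensing genes, 8 rose and 5 fell on both adjustments (camera adjusted p = 0.960); Ifi204 fell by 1.72 and Dhx9 rose by 0.74.

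Antigen presentation genes moved both ways. Of 21 MHC class I presentation genes, 7 rose and 9 fell (7 and 11 adjusted over the list alone), and camera did not call the list (adjusted p = 0.886). The classical class I genes H2-K1 and H2-D1 fell by 0.42 (SE 0.0404) and 0.46 (SE 0.0353) on the log2 scale, from 318 ± 7.94 to 238 ± 1.66 CPM and from 708 ± 25.8 to 514 ± 5.51 CPM. Nlrc5, the class I transactivator, fell by 0.77 (SE 0.145); it lies on chromosome 8, and with chromosome medians removed its value was -0.36. Pdia3, a chaperone of the peptide loading complex, rose by 0.64. B2m fell by 0.17 (SE 0.0364, adjusted p = 7.39e-05) and Tap1 by 0.19 (SE 0.0754, adjusted p = 0.0223). Both calls were lost with library size alone (-0.05 and -0.07) and with upper-quartile scaling (-0.009 and -0.035). That of Tap1 was also lost with the stricter filter (edgeR adjusted p = 0.0566) and without wild-type replicate 3 (adjusted p = 0.102). It was lost as well without either of 2 knock-out libraries (adjusted p = 0.0557 and 0.0517).

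Cd274, which encodes the checkpoint ligand PD-L1, fell from 15.7 ± 0.744 to 5.74 ± 1.40 CPM (log2 fold change -1.45, SE 0.175, adjusted p = 1.62e-10). Among 15 immune checkpoint and costimulatory ligands, 6 rose and 6 fell on both adjustments, with a median of -0.11 against a mean of 0.38 (camera adjusted p = 0.499); the median was 0.05 with upper-quartile scaling and 0.01 with library size alone. Pvr, the ligand of TIGIT, fell by 1.52 and Cd47, a signal against phagocytosis, by 0.74. These 2 had the smallest p of the list and Cd274 was chosen in advance, so the 6 that rose are not named. Of 17 chemokines and cytokines, 5 rose and 8 fell on both adjustments (camera adjusted p = 0.499); the macrophage growth factor Csf1 fell by 1.08 and Vegfa by 0.84. Ccl2, a monocyte attractant, had 1 count in wild-type and 105 in the knock-out, a ratio of 104 (95% interval 18.2 to 4137). Ccl5 had 4.03 ± 0.318 and 3.61 ± 0.123 CPM (adjusted p = 0.619). Of 18 NF-kB target genes, 9 rose and 9 fell on both adjustments (camera adjusted p = 0.131), with a median of -0.13 that was 0.03 with upper-quartile scaling and 0.11 with chromosome medians removed. Ptgs2, the inducible cyclooxygenase, fell from 1403 ± 53.7 to 231 ± 7.54 CPM and Tnfaip2 by 0.61 on the log2 scale.

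**Figure D3:**
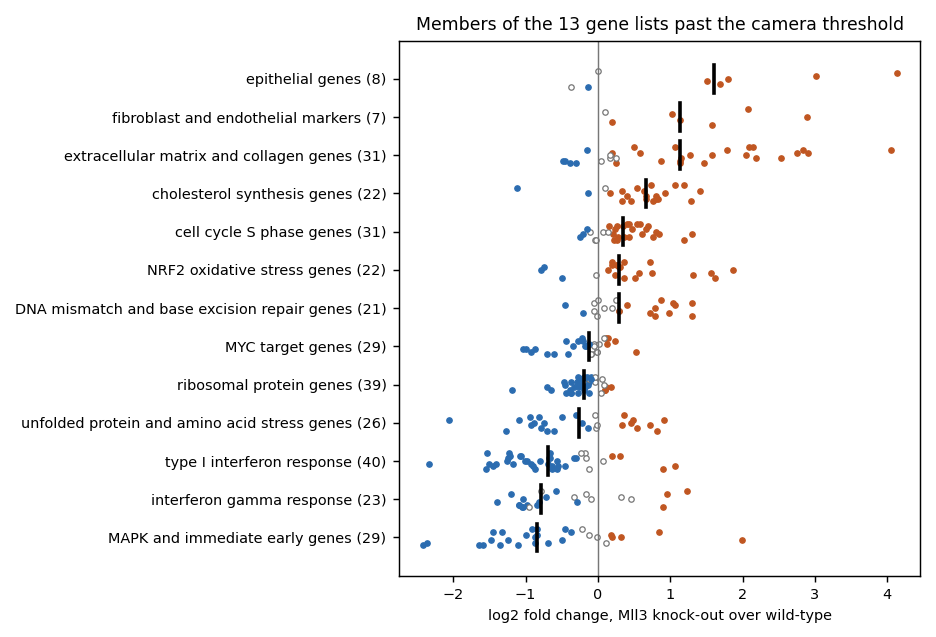
Log2 fold changes (horizontal axis, knock-out over wild-type) of the tested members of the 13 lists past the camera threshold; filled points passed the edgeR threshold, open points did not, black bars are list medians and the number tested is in parentheses. Medians run from -0.84 for MAPK and immediate early genes to 1.60 for epithelial genes.

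Extracellular matrix and collagen genes were higher in the knock-out. Of 31 tested, 22 rose and 5 fell on both adjustments, with a median log2 fold change of 1.13 (camera adjusted p = 1.19e-11, and 0.0239 with an estimated correlation). Col3a1, the collagen III chain, rose from 30.4 ± 1.56 to 217 ± 1.45 CPM. The thrombospondins Thbs1 and Thbs2 had log2 fold changes of 2.09 and 1.13, and Nid1, a basement membrane linker, had 1.78. Of the 7 tested fibroblast and endothelial markers, 6 rose and 0 fell on both adjustments (camera adjusted p = 0.00494; adjusted p = 0.211 with an estimated correlation). Of these 7, the matrix list also holds 3, Col1a1, Col1a2 and Dcn, so the calls are not separate. The smallest p were those of Col1a1 (1.58), Des (desmin, 2.90), Col1a2 (0.20) and Pdgfra (1.03). Of the 8 epithelial genes tested, 5 rose and 1 fell on both adjustments (camera adjusted p = 0.00282; adjusted p = 0.149 with an estimated correlation): the keratins Krt18, Krt20 and Krt7 rose by 1.51, 1.79 and 3.01 and the junction protein Jup by 1.69, while 19 of the 27 listed, Cdh1 and Epcam among them, were not tested. Of 18 mesenchymal transition genes, 7 rose and 7 fell on both adjustments (camera adjusted p = 0.899); the repressor Snai2 fell by 1.90 and Vim (vimentin) rose by 0.94. Of 5 immune cell markers tested out of 23, 3 rose and 1 fell on both adjustments (camera adjusted p = 0.437). Lyz2 stood at 0.553 ± 0.307 and 8.80 ± 0.535 CPM, and Csf1r, on chromosome 18, was lower by 1.19 (-0.79 with chromosome medians removed). Another of the 5 had 0 counts in 1 genotype, and the list had a mean of 2.10 against a median of 0.54.

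Genes of the S phase, and those of mismatch and base excision repair, were higher as lists. Of 31 S phase genes, 23 rose and 3 fell on both adjustments, with a median of 0.35, or 0.60 with chromosome medians removed (camera adjusted p = 0.00115; adjusted p = 0.149 with an estimated correlation). The helicase subunits Mcm7 and Mcm4, Uhrf1 and the cyclin Ccne1 rose by 0.70, 0.85, 0.76 and 1.19. Of 21 mismatch and base excision repair genes, 11 rose and 2 fell on both adjustments (camera adjusted p = 0.00494; adjusted p = 0.149 with an estimated correlation). Their median was 0.29, or 0.51 with chromosome medians removed, with log2 fold changes of 1.30 for Apex1, 1.04 for Parp1 and 0.88 for Msh6. Of 33 homologous recombination and Fanconi genes, 9 rose and 2 fell on both adjustments (camera adjusted p = 0.490); Exo1 rose by 0.97 and the end resection factor Rbbp8 fell by 1.55. The 31 G2 and M phase genes were split, with 10 higher and 9 lower on both adjustments (camera adjusted p = 0.865), with a median of -0.01 that was 0.15 with upper-quartile scaling and 0.11 with library size alone, and Mki67 and Prc1 fell by 0.77 and 0.70. Of 23 p53 targets, 14 rose and 5 fell on both adjustments (camera adjusted p = 0.165, but 0.0339 without wild-type replicate 2 and 0.00941 with no filter), yet the members with the smallest p fell: Gadd45a with -2.66 and Plk2 with -1.66.

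Cholesterol synthesis genes rose as a group, with 19 of 22 higher and 2 lower on both adjustments and a median of 0.67 (camera adjusted p = 0.00201; adjusted p = 0.211 with an estimated correlation). Hmgcs1, Fdft1 (chromosome 14) and Insig1 rose by 1.18, 0.93 and 0.80, and the sterol oxidase Msmo1, on chromosome 8, fell by 1.12; with chromosome medians removed Fdft1 had 0.62 and Msmo1 -0.70. Of 22 NRF2 oxidative stress genes, 18 rose and 3 fell on both adjustments (camera adjusted p = 0.00173; adjusted p = 0.213 with an estimated correlation); Pgd and Tkt of the pentose phosphate pathway rose by 1.31 and 0.72 (Tkt, on chromosome 14, by 0.41 with chromosome medians removed), the peroxiredoxin Prdx1 by 0.57 and Gstm1, one of several similar glutathione transferases, by 1.86. Unfolded protein and amino acid stress genes were lower, 15 of 26 falling and 8 rising on both adjustments (camera adjusted p = 0.000436; adjusted p = 0.176 with an estimated correlation). Log2 fold changes were -2.06 for Ppp1r15a (GADD34), -0.94 for the ER chaperone Hspa5 (BiP), -1.27 for asparagine synthetase (Asns) and -0.88 for the serine synthesis enzyme Phgdh.

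Of 39 ribosomal protein genes, 29 fell and 4 rose on both adjustments, with a median of -0.19 (camera adjusted p = 0.00194; adjusted p = 0.448 with an estimated correlation). The median was -0.03 with upper-quartile scaling and -0.07 with library size alone, where camera gave an adjusted p of 0.0489. Rps14, on chromosome 18, fell by 1.18 and Rpl13, on chromosome 8, by 0.70 (-0.78 and -0.28 with chromosome medians removed), Rpl3 by 0.64 and Rpl8 by 0.46. Ribosomal protein genes share reads with pseudogenes. Of 29 MYC targets, 15 fell and 5 rose on both adjustments (camera adjusted p = 0.0104; adjusted p = 0.337 with an estimated correlation), with a median of -0.12 that was 0.04 with upper-quartile scaling and 0.00 with library size alone, where camera no longer called the list (adjusted p = 0.0760). Myc itself fell from 305 ± 6.70 to 168 ± 2.26 CPM, and the snoRNP proteins Nop58 and Nop56 and the ribosome biogenesis factor Wdr43 fell by 1.04, 0.92 and 0.71.

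The remaining lists were not called by camera, and the counts on both adjustments were equal unless stated. Of 23 TGF-beta pathway genes, 11 rose and 6 fell (adjusted p = 0.128): the ligand Tgfb3 rose from 9.62 ± 0.257 to 62.5 ± 2.54 CPM and the inhibitor Smad7 fell by 1.84. Among WNT targets, 7 of 14 rose and 6 fell (adjusted p = 0.655), with Dkk2, a WNT antagonist, at 2.45 and Myc at -0.86. Of 14 Hox genes, 10 rose and 1 fell (adjusted p = 0.137), with Hoxc6 at 1.13 and Hoxb9 at -1.38. Of 38 chromatin writers and erasers, 12 rose and 20 fell, 21 over the list alone (adjusted p = 0.490), with the demethylase gene Kdm6b at -1.52 and the deacetylase gene Hdac9 at 1.86. Of 29 ferroptosis and apoptosis genes, 17 rose and 8 fell (adjusted p = 0.490), with Slc3a2 at -1.06 and the transferrin receptor Tfrc at 1.03. Of 19 hypoxia genes, 8 rose and 8 fell (adjusted p = 0.696), with Ndrg1 at -1.14. Glycolysis genes were 7 higher and 8 lower of 19 (adjusted p = 0.730), with Pfkl at 0.64 and Hk1 at 0.68, both on chromosome 10 (0.34 and 0.38 with chromosome medians removed). Fatty acid metabolism genes were 12 higher and 9 lower of 26 (adjusted p = 0.806), with Plin2 at -1.08 and Acadm at -1.39. Oxidative phosphorylation genes were 11 higher and 12 lower of 38 (adjusted p = 0.998), with Cycs at -0.48 and Uqcrq at -0.56. Of 12 mitochondrially encoded genes, 2 rose and 4 fell (adjusted p = 0.600), with mt-Rnr1 at -0.82 and mt-Nd2 at -0.22, a call lost with upper-quartile scaling (-0.06, adjusted p = 0.0623); the list's median of -0.06 was above 0 with upper-quartile scaling and library size alone. With 3 of 19 members tested, the replication-dependent histone list was too small for camera; Hist1h1c fell by 1.11 and Hist1h2bc had -0.68 (adjusted p = 0.0736), which passed without wild-type replicate 3 (-0.93, adjusted p = 0.0150).

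In all, camera called 13 of 35 lists at the preset correlation, 7 higher and 6 lower, and with an estimated correlation the calls of the matrix list and the MAPK list held. Fry called 27. Median, mean and test differed in sign for the checkpoint, chemokine, hypoxia, oxidative phosphorylation, mesenchymal, G2 and M phase, other COMPASS, and interferon receptor lists, none of them called by camera.

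Fold changes differed by chromosome. Over 9378 genes with an average log2 CPM of at least 3, whose median was -0.06, the median was -0.42 for 523 genes of chromosome 8 and -0.40 for 234 genes of chromosome 18, and it was 0.30 for 446 genes of chromosome 10 and 0.31 for 329 genes of chromosome 14. On chromosome 8, 79.5% of genes had a value below 0, and on chromosome 14, 75.4% had one above 0. All 13 windows of 10 Mb on chromosome 8 had a median below 0, and all 13 on chromosome 10 and all 9 on chromosome 14 had one above 0. On chromosome 18, 8 of 9 windows were below 0, from -0.85 to 0.09. Chromosomes 1, 3 and 19 had medians of -0.26, -0.24 and -0.22; on chromosome 3 the windows from 100000001 to 160000000 ran from -0.82 to -0.40. The signs of these 7 medians held with all 4 scalings. Removing a chromosome's median does not remove regional shifts. On chromosome 18 the window median was -0.85 around Cxxc1 and Smad7, -0.54 around Csf1r and Rps14 and -0.52 around Rbbp8. On chromosome 3 it was -0.78 around Acadm and Ifi44 and -0.43 around Csf1. On chromosome 5, whose median was -0.07, it was -0.38 around Ereg and Cxcl10. On chromosome 15, whose median was 0.08, it was 0.45 around Krt18, Krt7 and Hoxc6.

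**Figure D4:**
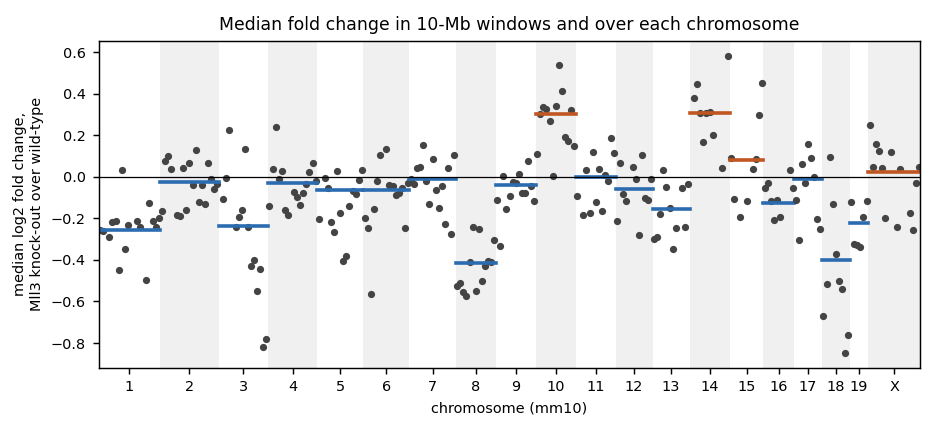
Median log2 fold change (vertical axis, knock-out over wild-type) along the mm10 chromosomes (horizontal axis); each point is a 10-Mb window with at least 10 genes, and each coloured line is the median of a chromosome. Chromosomes 8 and 18 lie near -0.4, and 10 and 14 near 0.3.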

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

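Of 131 named genes other than Kmt2c, 109 kept their direction and their side of the threshold in all alternatives that could test them, 22 lost or gained the threshold in at least 1 and 2 changed sign. Kmt2c kept both throughout. Most of the 131 genes were chosen for a large change or a small p in these same libraries, so this stability was partly built in. Against a 1.5-fold change, glmTreat called 2602 genes (1448 higher, 1154 lower) and 19 named genes lost the call, since the null hypothesis is wider. The stricter filter gave 1248 genes changed at least 2-fold among 10837 tested, since it removes weakly expressed genes. Estimating the correlation left 2 lists, since camera then refers each list to the few residual degrees of freedom of 6 libraries, beside its own correlation; fry gave 27, since it asks another question. Kdm6a changed sign with upper-quartile scaling (0.0062), because that scaling moves all genes up alike. Ash2l did so when chromosome medians were removed (0.0055), because it lies on chromosome 8; that alternative was chosen after seeing the data and gave 8423 changed genes, 7730 of them shared. With 1 library left out, changed genes numbered 8082 to 8717, higher genes 3902 to 4295, lower genes 4083 to 4422, 2-fold changes 1989 to 2143, lists 13 to 14 (p53 targets were added without wild-type replicate 2), and Kmt2c ran from -0.98 to -0.73. Calls of DESeq2 (8217) and limma voom (8660) shared 7842 and 8554 genes with edgeR. No paired analysis was possible because the knock-out columns carry no replicate number that the labels give. At this depth 3 counts are 0.224 to 0.314 CPM, and 4705 weakly counted genes were not tested.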

Other observations

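The tests of gene length and abundance bias, of the lists after removal of chromosome medians and of fibroblast transcripts were chosen after the patterns had been seen, as were the gene families and genes of the next paragraph.

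Grouping the tested genes by the letters that open their symbols gave 192 families with at least 8 members, of which camera called 7, 4 higher and 3 lower; with an estimated correlation none held (adjusted p = 0.958 for each). Small nucleolar RNA host genes were lower, 8 of 11 falling and 1 rising, with Snhg1 falling from 339 ± 16.5 to 93.4 ± 7.92 CPM, Snhg17 by 1.24 and Snhg12 by 1.42 on the log2 scale (camera adjusted p = 0.00762). Annexins were higher, 6 of 9 rising and 2 falling, with Anxa8 going from 19.9 ± 2.42 to 79.8 ± 0.394 CPM and Anxa5 from 612 ± 9.62 to 892 ± 0.689 CPM (camera adjusted p = 0.0369). Of 53 protein phosphatase genes, 30 fell and 7 rose (camera adjusted p = 0.00762), Ppp2cb by 0.80 and Ppp2r2a by 0.77. The interferon-inducible Ifi genes, the collagens, the Mcm genes and the matrix metalloproteinases made up the other 4 families and overlap the fixed lists. Outside every list, Chka, the choline kinase gene, fell from 635 ± 22.0 to 80.0 ± 2.69 CPM. In all, 30 genes reached at least 2 CPM in 1 genotype with a fitted log2 fold change of at least 5 in size, 14 in the knock-out and 16 in wild-type; Ramp3, a receptor activity-modifying protein, was at least 7.29-fold higher and Fibin at least 9.27-fold lower.

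The 6 libraries can be split 10 ways into 3 and 3, so no share under 0.05 can be reached. The real split gave 8621 changed genes and the highest other split 0; for lists it gave 13 and the highest other split 10, and in each case 1 of the 10 splits, the real one, gave as many. Each other split mixes the genotypes unevenly and so keeps part of the difference between them. The rest of that difference widens the spread within its groups, which leaves little room for gene calls. The counts of 8621 and 0 therefore say nothing about chance.

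The chromosome-wide shifts form the first pattern. Turning the fold changes along the genome by 10000 random offsets gave a spread of chromosome medians as large with a permutation p of 0.0004 (SD 0.185), which argues against a chance arrangement, and a trend on genomic length and abundance, with an SD of 0.138 over genes, had chromosome medians with an SD of 0.0199; removing it left 0.183, which argues against those biases. A candidate explanation is that the cultures differ in chromosome copy number. Under it, 255 genes of the ribosomes, proteasome and respiratory chain should follow the other genes of their chromosome with a slope near 1. The slope was 0.58 (95% bootstrap interval 0.27 to 0.87, permutation p = 0.0001, the smallest these permutations can give). The bootstrap drew genes singly, although the genes of a chromosome share 1 predictor value, so the interval may be too narrow. It lies below 1 and also reaches below the bound of 0.3 set in advance. Copy number therefore cannot be told apart from other causes here. Whether such a difference came with the knock-out or with the history of the cultures stays open, since genotype and culture coincide and DNA was not measured in these samples.

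The lower interferon response is the second pattern. With chromosome medians removed, the type I list still had a median of -0.78 and was still called by camera, so chromosome-wide shifts are not its whole cause. Shifts of smaller regions, such as that around Ifi44, were not removed. Immune cells in the wild-type cultures would bring leukocyte transcripts. Of 6 checked, Tyrobp, C1qa and C1qb are not among the deposited genes. The highest in wild-type, Lyz2, stood at 0.553 ± 0.307 CPM, against a summed 4641 CPM for the interferon list. Csf1r, a listed immune cell marker outside these 6, stood at 15.2 ± 1.02 CPM in wild-type and 6.72 ± 1.55 CPM in the knock-out. Cells that carry it are thus not excluded. An effect of the genotype on basal interferon signalling is a hypothesis that remains open beside differences between cultures, and the call does not hold with an estimated correlation (adjusted p = 0.135).

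The higher matrix expression is the third pattern. With chromosome medians removed, the median of the list was 1.10, and camera still called it. Fibroblasts in the knock-out cultures should bring their other abundant matrix transcripts; of 9 checked, 6 (Lum, Postn, Lox, Cdh11, Thy1 and Eln) are not among the deposited genes and the highest, Col12a1, stood at 0.899 ± 0.554 CPM in the knock-out, while Col3a1 gained 187 CPM. That argues only against fibroblasts that carry these 9 transcripts, a set chosen after the pattern was seen. Outside that set, Col1a1 (95.1 to 283 CPM), Col1a2 (880 to 1009 CPM) and Pdgfra (4.65 to 9.57 CPM) rose. Des (0.708 to 5.46 CPM) and Acta2 (0.141 to 4.27 CPM) rose as well. Of the 7 tested fibroblast and endothelial markers, 6 rose and 0 fell, so other fibroblasts and mesenchymal cells are not excluded. Genotype and differences between cultures, in density for example, stay open and were not tested.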
